A study of Mus musculus with 5 samples.

How the data were processed

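Chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is isolated with an antibody and sequenced, had been carried out in LF2 cells, a mouse embryonic stem (ES) cell line. There was 1 library each for Jarid2, Ezh2, Suz12 and Jarid1a, and 1 library of total input DNA. Per the labels' protocols, nuclei were sonicated, bound DNA was isolated with antibody, adapters were ligated, and fragments were amplified by PCR, size-selected on a gel and sequenced on an Illumina Genome Analyzer. Groups were taken from the antibody label, and from the sample description for input. No antibody had a replicate library, so no p-value was computed and no difference has a replicate check.

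The deposited tag files hold 1 line per aligned read, with its position and strand on build mm9, per the file headers. The deposited site lists hold called regions and, inside them, peak positions, each with a score that is the authors' own value, and the file headers describe the lists as filtered. The unit of the score, the caller, the control used for calling, the filters, the aligner and all versions are not given in the sources used here. The score was used only to rank sites within a list. Each antibody has its own file of sites and its own numbering.

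The filters applied by the authors affect which sites could coincide, so tags were also counted at sites called with another antibody, whether or not a call had been made in the library counted. Of the deposited tags, those on chromosomes 1 to 19, X and Y were used, with at most 1 tag per position and strand, because reads amplified by PCR without molecular identifiers are not independent molecules. Each tag's 5′ end was moved 75 bp downstream. A site was a deposited region, placed at its highest-scoring peak position. Enrichment was log2 of ChIP over input tags, each per 1000000 tags of its library, within 1 kb on each side of the site, with a pseudocount of 1 input tag, scaled to library size for the ChIP.

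Site lists were compared by the share of sites with a partner centre within 1 kb, with a Wilson 95% interval, beside 1000 random placements on the same chromosomes. Because input itself was higher at sites than elsewhere, 1000 placements among 2 kb bins with at least the sites' median input count were added after the data had been seen. Median enrichments carry a 95% interval from order statistics, and enrichments of single sites carry an exact Clopper-Pearson 95% interval from both tag counts. All of these intervals cover counting error or the spread over sites only. Spearman correlations were computed across 2 kb bins, which are not independent replicates. The spread of the Jarid2 to Suz12 ratio was set beside the spread that binomial counting error alone gave.

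No annotation of build mm9 was used here. The gene table at hand is on assembly GRCm38.p6, and its coordinates were not mixed with those of the files. The planned shares of sites near transcription starts and the planned gene lists were therefore not run, sites are named by position, and the correlations planned across promoters were run across 2 kb bins holding at least 1 site. The sites named are the 5 with the highest score in each list, and the 3 highest and the 3 lowest Jarid2 to Suz12 ratios among Jarid2 and Suz12 sites with at least 50 tags in both libraries together. Tests, samples, alternatives and this rule were fixed before the data were examined, and later additions are named as such.

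The alternatives changed the partner distance, the list lengths, the score and enrichment thresholds, the treatment of repeated tags, the scaling, the pseudocount, the window, the tag shift, the depth and the input minimum. The functions were tested on simulated data. At 200 simulated sites per fold, the median log2 enrichment came out -0.06 from the true value at 1-fold, -0.06 at 4-fold and -0.09 at 16-fold. An overlap of 60% among 600 simulated sites was recovered as 60%, and a simulated ratio spread of 0.5 (SD of log2) was recovered as 0.51. The simulated input was even, and simulated partners lay well inside or outside the 1 kb limit. These checks thus cover the arithmetic, not the effects of uneven input or repeated tags. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.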

Results

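The series mapped where Jarid2 lies on the genome of LF2 mouse ES cells relative to Polycomb repressive complex 2 (PRC2), a histone methyltransferase complex that represses developmental genes. Ezh2 is the catalytic subunit of PRC2 and Suz12 one of its core subunits. Jarid2 belongs to the Jumonji/ARID family and lacks the demethylase activity of its relatives. Jarid1a, also called Kdm5a, is a histone demethylase of the same family. The tag files held 13531375 tags for Jarid2, 12733679 for Ezh2, 18659331 for Suz12, 10937576 for Jarid1a and 28471141 for input.

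Repeated tags differed between the libraries. Distinct positions made up 55.8% of the tags of Jarid2, 54.9% of Ezh2 and 33.6% of input, but 91.2% of Suz12 and 96.6% of Jarid1a. After repeats were removed, 7539823 Jarid2, 6990242 Ezh2, 17022193 Suz12, 10533248 Jarid1a and 9568310 input tags remained. The Jarid2, Ezh2 and input libraries also shared a feature of the minus strand, where between 17.4% (Jarid2) and 26.7% (input) of distinct positions lay 1 bp after another. On the plus strand the shares lay between 0.844% (input) and 1.53% (Ezh2). Suz12 had 4.68% on either strand and Jarid1a 1.14%. The libraries thus fell into a set of Jarid2, Ezh2 and input and a set of Suz12 and Jarid1a, so a difference between Jarid2 or Ezh2 and Suz12 cannot be separated from this division.

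The deposited lists held 1336 Jarid2, 1695 Ezh2, 2070 Suz12 and 1764 Jarid1a regions. Regions of Jarid2 and the PRC2 subunits were broad, with a median width of 2738 bp for Jarid2, 3112 bp for Ezh2 and 4093 bp for Suz12, and the widest Suz12 region covered 54994 bp. Jarid1a regions were narrow, with a median of 858 bp. Several peaks were marked in 432 Jarid2, 622 Ezh2 and 845 Suz12 regions and in 0 Jarid1a regions. The share of a library's distinct tags inside its own regions was 5.22% for Jarid2, 7.61% for Ezh2, 13.7% for Suz12 and 2.15% for Jarid1a.

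Most Jarid2 sites lay at sites of PRC2. An Ezh2 centre lay within 1 kb of 1189 of the 1336 Jarid2 sites, 89.0% (95% interval 87.2 to 90.6%), and a Suz12 centre within 1 kb of 967, 72.4% (69.9 to 74.7%). Ezh2 sites had a Suz12 centre in 68.6% (66.4 to 70.8%) and a Jarid2 centre in 70.1% (67.9 to 72.3%). Of the 2070 Suz12 sites, 46.7% (44.6 to 48.9%) had a Jarid2 centre and 56.2% (54.0 to 58.3%) an Ezh2 centre. When the 3 lists were joined into 2408 merged regions, 1074 (44.6%) held calls of Jarid2, Ezh2 and Suz12, 676 (28.1%) of Suz12 alone, 202 (8.39%) of Ezh2 alone and 24 (0.997%) of Jarid2 alone.

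Random placement of Jarid2 sites put a mean of 0.135% near an Ezh2 centre and 0.171% near a Suz12 centre. Placement in bins with at least the sites' median of 23 input tags, added after the data had been seen, put 7.13% and 6.45% there. The 967 Jarid2 and the 967 Suz12 sites with a partner in the other list are equal in number, so the lower share among Suz12 sites follows from the longer Suz12 list. With each list limited to its 1336 highest-scoring sites, 58.5% of Jarid2 sites had a Suz12 partner and, by arithmetic, the same share of Suz12 sites a Jarid2 partner.

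**Figure D1:**
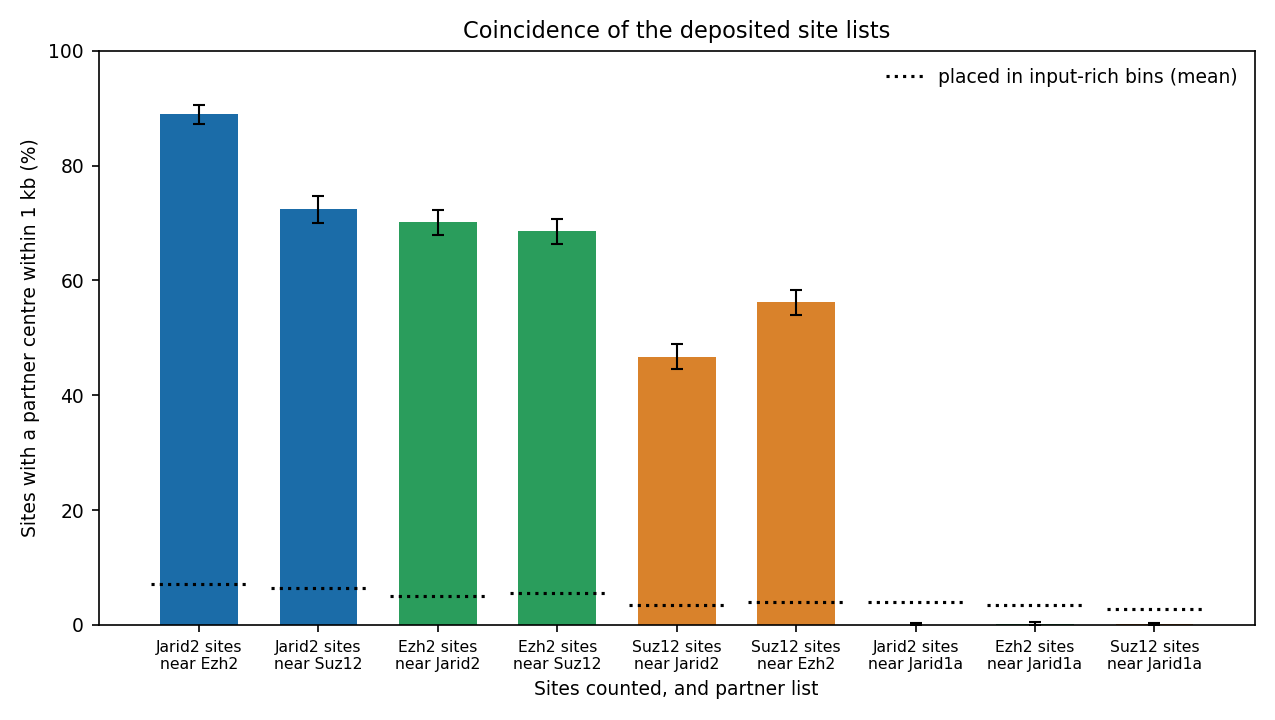
Bars give the percentage of sites of each list with a centre of the partner list within 1 kb, error bars the Wilson 95% interval, and dotted lines the mean of 1000 placements in input-rich 2 kb bins. Jarid2, Ezh2 and Suz12 sites had a partner in 46.7 to 89.0% of cases, and at most 0.177% of them had a Jarid1a partner.

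Tag counts at sites of another antibody, which do not depend on a call in the library counted, gave the same arrangement. At Suz12 sites the median Jarid2 enrichment was 8.55-fold over input (log2 3.10, 95% interval 3.04 to 3.14), and 1848 of the 2070 sites (89.3%) had at least 4-fold. At Jarid2 sites, Ezh2 was enriched 12.5-fold (log2 3.64, 3.60 to 3.67) and Suz12 15.6-fold (log2 3.97, 3.93 to 4.02). Jarid2 itself was enriched 10.9-fold at its own sites (log2 3.44, 3.40 to 3.47). Values of a library at its own sites, here and in the density ratios below, do depend on the call and on the placing of the centre. Median log2 enrichment at random placements on the same chromosomes was -0.036 for Jarid2, -0.094 for Ezh2 and -0.42 for Suz12. At 5 to 6 kb from Jarid2 sites the mean density of Suz12 tags was 2.95 tags per kb (per 1000000 tags of the library), against 1.37 for Jarid2, 1.73 for Ezh2 and 0.524 for input. At Suz12 sites the density at the centre was 14.4 times that at 5 to 6 kb for Suz12, 15.2 times for Jarid2 and 14.1 times for Ezh2. There it was 2.72 times for input and 3.53 times for Jarid1a. At Jarid2 sites the ratio was 9.60 for Suz12, 27.1 for Jarid2, 21.2 for Ezh2 and 4.39 for input. At Ezh2 sites it was 10.7 for Suz12, 27.5 for Jarid2, 26.6 for Ezh2 and 4.41 for input.

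Suz12 sites without a Jarid2 centre nearby also carried Jarid2 tags. Among the 1103 Suz12 sites with no Jarid2 centre within 1 kb, the median Jarid2 enrichment was 6.07-fold (log2 2.60, 95% interval 2.56 to 2.64), against 10.9-fold (log2 3.44, 3.40 to 3.49) at the 967 sites with one, a direction that follows from the split by Jarid2 call. Of the 1103, 166 lay in a region overlapping a Jarid2 region, and at the other 937 the median was 5.69-fold (log2 2.51, 2.44 to 2.56). The median Suz12 enrichment was 15.7-fold at all 1103 sites without a Jarid2 centre and 16.5-fold at the 967 with one. In the opposite direction, the 369 Jarid2 sites without a Suz12 centre had a median Suz12 enrichment of 13.7-fold (log2 3.77, 3.70 to 3.86), and 215 of their regions overlapped a Suz12 region. At the other 154 it was 9.52-fold. Input was not even across the genome. The median count within 1 kb was 23 tags at Jarid2 sites, 22 at Ezh2 sites, 20 at Suz12 sites and 18 at Jarid1a sites, against 7 at random placements.

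**Figure D2:**
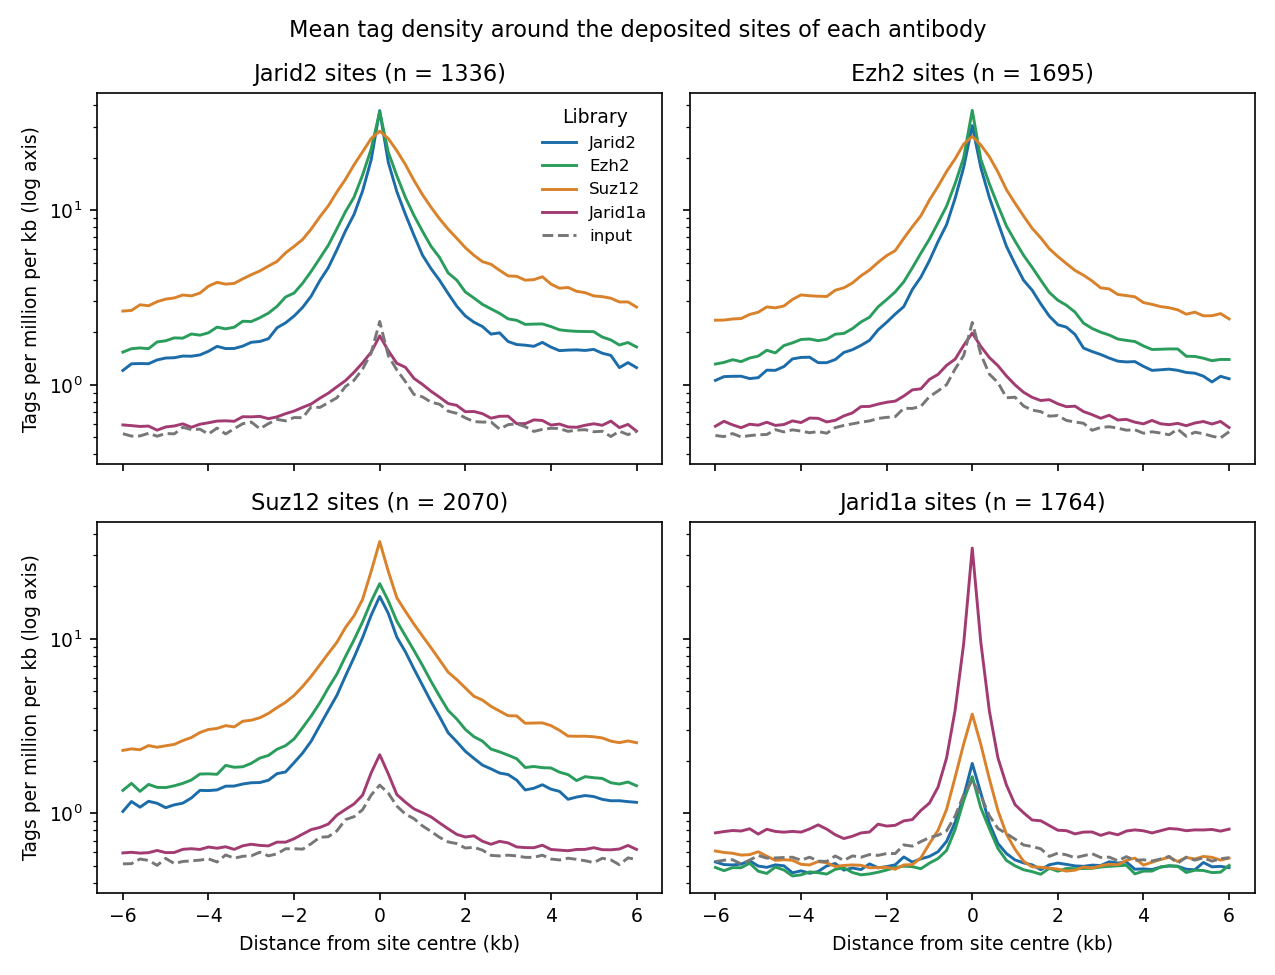
Each panel shows the sites of 1 antibody, with distance from the site centre in kb on the x axis and mean tags per kb, per 1000000 tags of the library, on a log y axis, and a line per library (input dashed). At the centre of Jarid2 sites the mean densities were 37.1 for Jarid2, 36.6 for Ezh2, 28.3 for Suz12, 1.91 for Jarid1a and 2.30 for input.

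Called Jarid1a sites lay apart from those of PRC2. Of the 1764 Jarid1a sites, 2 had a Suz12 centre within 1 kb (0.113%, 95% interval 0.0311 to 0.412%), 1 had a Jarid2 centre (0.0567%, 0.0100 to 0.320%) and 3 had an Ezh2 centre (0.170%, 0.0579 to 0.499%). The share of Jarid2 sites with a Jarid1a centre was 0.0749% (0.0132 to 0.423%). These numbers were near those of random placement, which put a mean of 3.13 Jarid1a sites near Suz12 and 1.89 near Jarid2. They lay below all 1000 input-rich placements, which put at least 28 Jarid1a sites near Suz12 and at least 20 near Jarid2. Those bins all held at least 18 input tags, the median of Jarid1a sites, while the lower quartile of the sites was 14. Sites below the median were thus not matched, and the placements may overstate the number to be reached without avoidance. Named after their values were seen, the sites near Suz12 were at mm9 chromosome 1, 9534990 to 9536354, and chromosome 8, 74031435 to 74032213.

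Jarid1a was enriched 6.29-fold at its own sites (log2 2.65, 95% interval 2.62 to 2.70). At Jarid2 sites its median was 1.03-fold (log2 0.044, 0.0033 to 0.091) and at Suz12 sites 1.22-fold (log2 0.28, 0.25 to 0.32). At Jarid1a sites, Jarid2 was at 0.921-fold (log2 -0.12, -0.15 to -0.069) and Ezh2 at 0.797-fold (log2 -0.33, -0.37 to -0.29), while Suz12 was at 1.51-fold (log2 0.60, 0.57 to 0.62). Random placements gave -0.035, -0.092 and -0.40 for Jarid2, Ezh2 and Suz12. The sign of Jarid1a at Jarid2 sites changed under some alternatives, such as -0.12 with a window of 500 bp on each side. Jarid2 and Ezh2 at Jarid1a sites stayed negative as enrichments over input. Their signs changed only where the median of windows matched on input was subtracted, which is a different measure. The Suz12 value at Jarid1a sites fell to log2 0.17 with a window of 2.5 kb on each side.

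**Figure D3:**
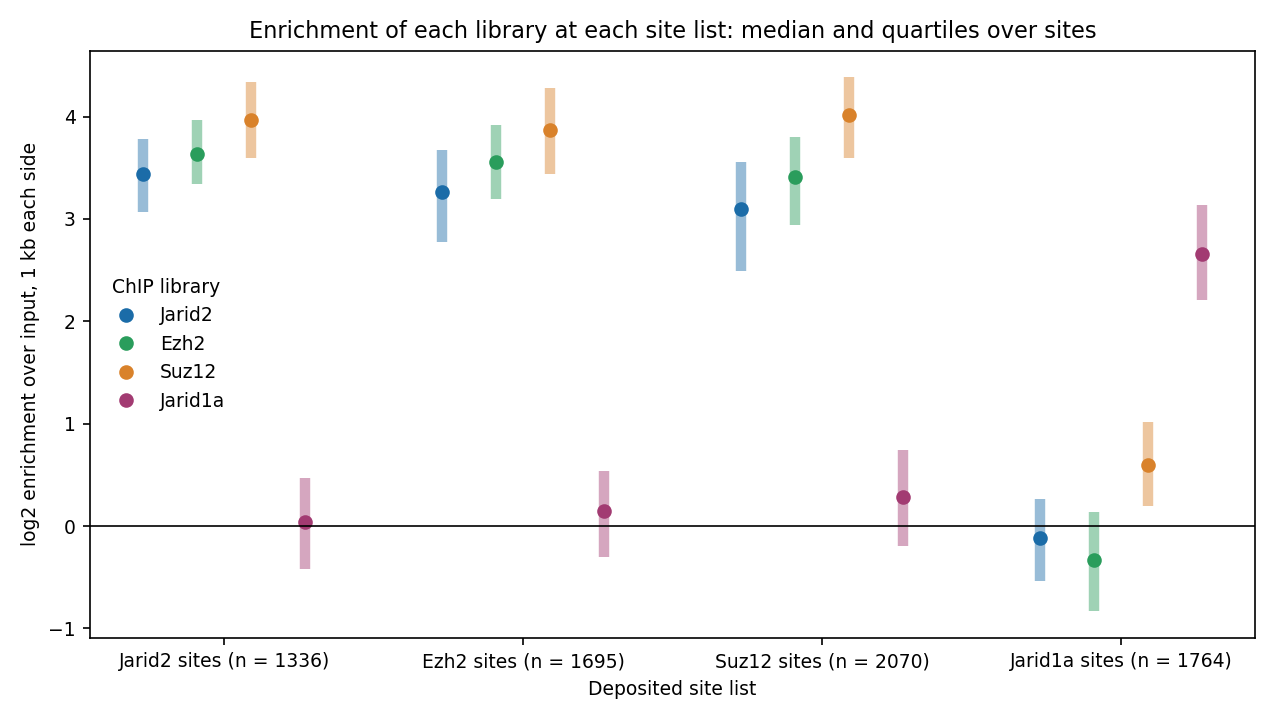
Points give the median and bars the quartiles over sites of log2 enrichment over input within 1 kb of the site centre, for each ChIP library at each list. Jarid2, Ezh2 and Suz12 medians lay between 3.10 and 4.02 at their own and each other's sites and between -0.33 and 0.60 at Jarid1a sites.

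Across the 4632 bins of 2 kb that held a site of any list, enrichments of Jarid2 and Ezh2 rose together most closely (Spearman rho 0.951), ahead of Ezh2 with Suz12 (0.899) and Jarid2 with Suz12 (0.887). Jarid1a ran opposite to Jarid2 (-0.704) and to Suz12 (-0.617). Without input, these values were 0.957, 0.917, 0.912, -0.680 and -0.657, and with the input tags split at random between the libraries of a pair they were 0.851, 0.805, 0.798, -0.745 and -0.677. The opposite course of Jarid1a rested on the choice of bins. In the 2873 bins holding a Jarid2, Ezh2 or Suz12 site, a choice made after the data had been seen, rho was -0.103 for Jarid1a with Jarid2 and 0.220 with Suz12, while Jarid2 and Ezh2 stayed at 0.930 and Jarid2 and Suz12 were at 0.661. Values over the same input share its counting error. With input split in these bins, rho was 0.595 for Jarid2 with Ezh2, 0.395 for Jarid2 with Suz12, -0.240 for Jarid1a with Jarid2 and -0.0035 with Suz12. Without input, rho in these bins was 0.958, 0.770, 0.038 and 0.1175 in that order. Each part of the split input holds fewer tags, which adds counting error of its own. The sign for Jarid1a with Jarid2 in these bins thus depended on the treatment of input. Jarid2 and Ezh2 lay within 1 of the library sets described above, and Jarid2 and Suz12 across them.

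The ratio of Jarid2 to Suz12 tags varied between sites by more than counting error. Across the 2439 sites of both lists, the SD of its log2 was 0.618, against 0.136 from counting error alone, and from the 5th to the 95th percentile it ran from -1.96 to 0.048. The corresponding SD was 0.524 for Ezh2 to Suz12 and 0.288 for Jarid2 to Ezh2, with 0.130 and 0.183 from counting error. The smallest spread was again between libraries of the same set.

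The highest-scoring Jarid2 site, at mm9 chromosome 11, 108872740 to 108873603, was enriched in every ChIP library. It had log2 2.18 (95% interval 1.81 to 2.59) for Jarid2, 2.03 (1.69 to 2.42) for Suz12 and 2.12 (1.76 to 2.52) for Jarid1a. It held 73 input tags, against a median of 23 at Jarid2 sites. It also ranked 2 in the Ezh2 list and 1 in the Suz12 list. The highest-scoring Ezh2 site, at chromosome 17, 39979745 to 39985997, held 460 input tags, against a median of 22 at Ezh2 sites. It had log2 2.01 (1.86 to 2.17) for Ezh2 and 1.77 (1.62 to 1.92) for Jarid1a. Jarid2 sites 3 and 5 by score, at chromosome 5, 147072120 to 147073197, and chromosome 17, 36367951 to 36368982, also had Jarid1a at log2 0.94 (0.44 to 1.48) and 1.63 (1.22 to 2.10).

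The other high-scoring sites of Jarid2, Ezh2 and Suz12 were broad and had no such Jarid1a signal. Jarid2 site 2, at chromosome 14, 58688172 to 58695887, had log2 3.61 (3.14 to 4.20) for Jarid2, 4.10 (3.65 to 4.68) for Suz12 and -1.26 (-2.30 to -0.40) for Jarid1a, and it overlapped Ezh2 site 4. Jarid2 site 4, at chromosome 11, 98186627 to 98191315, had 3.88 (3.46 to 4.39) for Jarid2 and -1.01 (-1.84 to -0.28) for Jarid1a. Ezh2 sites 3 and 5, at chromosome 8, 87320454 to 87325844 and 123637172 to 123647353, had Ezh2 at 4.77 (4.30 to 5.37) and 4.35 (3.91 to 4.90). Suz12 sites 2 to 5 had Suz12 between log2 4.38 and 5.35 and Jarid1a between -0.64 and 0.28. They lay at chromosome 8, 87292094 to 87315151 and 114412955 to 114416879, and at chromosome 9, 55386217 to 55395198 and 62978873 to 62999922.

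The 5 highest-scoring Jarid1a sites had Jarid1a between log2 3.72 and 4.60, or 13.1-fold to 24.2-fold, and Jarid2 between -1.40 and 0.47. The strongest of them by tags, at chromosome 8, 112088910 to 112090261, held 558 Jarid1a tags over 20 input tags (log2 4.60, 95% interval 4.02 to 5.39). The others lay at chromosome 4, 133130240 to 133131212, at chromosome 7, 133520332 to 133521284, and at chromosome 8, 87212769 to 87213884 and 113142206 to 113143174.

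The Jarid2 to Suz12 ratios given here are scaled to library size, while the tag counts beside them are not scaled. Among Jarid2 and Suz12 sites, the highest ratio, log2 1.68, was at chromosome 1, 121316269 to 121319763, with 343 Jarid2 and 242 Suz12 tags. The next were at chromosome 16, 22160960 to 22163875 (log2 1.61), and chromosome X, 84483439 to 84484044 (log2 1.41). Chromosome X as a whole held 4.06% of the distinct Jarid2 tags but 2.53% of those of Suz12, which goes toward a higher ratio at sites on it. The lowest, log2 -3.18, was at chromosome 6, 93628070 to 93629631, with 15 Jarid2 and 317 Suz12 tags, where Jarid1a was at log2 2.16 (1.23 to 3.49). Chromosome 12, 107200766 to 107202018, and chromosome 15, 102185315 to 102191101, followed with log2 -2.88 and -2.87.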

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

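The search for tag-rich bins, the look at mitochondrial tags and the tests of an explanation given here were chosen, or changed, only after the results were seen.

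Bins rich in Jarid1a tags also lay outside its deposited list. Bins of 2 kb that reached the median enrichment and tag count of bins at Jarid1a sites, 6.13-fold over input and 120 tags, numbered 735, and 75 of them (10.2%) lay outside the deposited Jarid1a regions. The corresponding numbers were 14 of 619 for Jarid2, 10 of 814 for Ezh2 and 7 of 1258 for Suz12, each set against its own list. Their bars were higher, at 10.1-fold and 174 tags for Jarid2, 11.3-fold and 173 tags for Ezh2, and 15.2-fold and 503 tags for Suz12. The counts of bins are therefore not comparable between libraries. Of the 14 Jarid2 bins, 13 lay in a region called for Ezh2 or Suz12, and of the 10 Ezh2 bins 9 lay in a region called for Jarid2 or Suz12. Of the 7 Suz12 bins, 3 lay in a region of another list. Of the 75 bins, the one with the most Jarid1a tags, at mm9 chromosome 2, 22444001 to 22446000, was chosen after its values were seen and held 609 Jarid1a, 163 Suz12, 68 Jarid2, 1 Ezh2 and 8 input tags. Suz12 and Jarid2 tags thus also exceeded input in this bin, so its signal was not particular to Jarid1a.

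Jarid1a sites almost never coincided with PRC2 sites, while 213 region numbers of the Jarid1a list are absent, against 1 for Jarid2, 0 for Ezh2 and 3 for Suz12. Had a filter removed Jarid1a sites at PRC2 regions, most of the 75 bins would lie there, and 2.67% did. This argues against a filter as the main cause only for sites reaching the bar of those bins, the median of bins at Jarid1a sites. Jarid1a was at least 4-fold at 17 of 2070 Suz12 sites (0.821%), against 85.3% of its own, which were called on these tags. Input-rich placements put a mean of 46.1 Jarid1a sites near Suz12, so the 17 do not exclude a filter for part of them. Single sites also stay open, such as the highest-scoring Jarid2 and Ezh2 sites with Jarid1a at 4.33-fold and 3.41-fold. There Jarid2 was at 4.52-fold and 4.53-fold, over 73 and 460 input tags, so the signal was not particular to Jarid1a. Jarid1a below the calling threshold was set to count as the cause where its median exceeded that of windows matched on input by at least log2 0.5, and over all Suz12 sites the difference was 0.136 (0.41 in a first version, matched on the tags that also formed the denominator), a median over sites that went both ways. At the 1394 Suz12 sites in a region overlapping a Jarid2 or Ezh2 region it was -0.119, from a site median of 0.079 and a window median of 0.198. Matching stayed incomplete, since the dividing input tags had a median of 10 over all Suz12 sites and 6 in the windows. The -0.119 thus argues against this at the 1394 sites only as far as the matching holds. At the other 676 the difference was 0.628 (median 95% interval 0.57 to 0.70), and 30.6% of these sites had at least 2-fold Jarid1a against 15.4% of the windows. At those 676 sites Jarid1a may thus be present below the threshold, and a background shared by the Suz12 and Jarid1a libraries also stays open.

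The share of tags on the mitochondrial genome, which no comparison used, was 0.314% in the Jarid1a library, above the 0.122% of input. It was 0.0833% for Jarid2, 0.0472% for Ezh2 and 0.0182% for Suz12.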

How the results depend on the processing

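Chosen only after the results were seen were the settings with every peak as a site, with adjacent minus-strand positions merged, with windows matched on input, with bins near PRC2 sites or far from all sites, and without sites high in all 4 ChIP libraries. Of the 198 alternative values for the 21 comparisons, 83 stayed within the interval of the reported value, 106 lay outside it with the same direction and 9 changed sign. Of the 200 for the 20 highest-scoring sites, 185 stayed within the interval, 15 lay outside it and 0 changed sign. Except where a construction is named, the cause was not tested.

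For Jarid2, Ezh2 and Suz12 sites, the shares near each other given here fell with the shorter distance and rose with the longer, the only directions possible by construction. Cutting a partner list also removes partners. Lower shares with cut lists thus need not mean weaker coincidence at higher-scoring sites. The share of Jarid2 sites near Suz12 (72.4%) was 55.8% within 500 bp, 79.8% within 2 kb and 88.5% for overlapping intervals. It was 60.0% for the higher-scoring part of each list, 58.5% for lists of equal length and 89.9% with every peak as a site. The share of Jarid2 sites near Ezh2 (89.0%) was 83.4% within 500 bp, 91.0% within 2 kb and 94.1% for overlapping intervals. It was 84.9% for the higher-scoring part of each list, 81.0% for lists of equal length and 94.8% with every peak as a site. The share of Ezh2 sites near Suz12 (68.6%) was 52.8% within 500 bp, 74.3% within 2 kb and 80.4% for overlapping intervals. It was 57.5% for the higher-scoring part of each list, 57.4% for lists of equal length and 84.9% with every peak as a site. The share of Suz12 sites near Jarid2 (46.7%) was 36.0% within 500 bp, 51.4% within 2 kb and 54.7% for overlapping intervals. It was 38.7% for the higher-scoring part of each list, 58.5% for lists of equal length and 55.8% with every peak as a site. The share of Jarid1a sites near Suz12 (0.113%) was 0% for the higher-scoring part of each list, and 0.170% within 2 kb and 0.340% for overlapping intervals, both within its interval. The share of Jarid1a sites near Jarid2 (0.057%) was 0% for the higher-scoring part of each list and 0% for sites at least 4-fold over input. The share of Jarid2 sites near Jarid1a (0.075%) was 0% for the higher-scoring part of each list and 0% for sites at least 4-fold over input. With 3 sites taken as the limit that a count of 0 allows, the shares of 0% allow up to 0.340% of the 882 higher-scoring Jarid1a sites, 0.449% of the 668 such Jarid2 sites, 0.199% of the 1504 Jarid1a sites at least 4-fold over input and 0.226% of the 1327 such Jarid2 sites.

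The medians of Jarid2 at Suz12 sites, and of Suz12 and Ezh2 at Jarid2 sites, stayed at log2 2.61 or above, and Suz12 at Jarid1a sites stayed above 0. The low median of Jarid1a at Jarid2 sites had no stable sign. Jarid2 and Ezh2 at Jarid1a sites stayed negative as enrichments over input. Less the median of matched windows, a different measure, Jarid2 was positive with either matching and Ezh2 only with windows matched on all input tags. Windows matched on all input tags were chosen on the count that is also their denominator, so chance-high counts lowered their enrichment. Matching on a random part of the input tags and dividing by the rest removed this, and the tests of explanations use those values. The change was made after the first values had been seen. Matching stayed incomplete, since at Jarid1a sites the rest held a median of 9 tags and in the windows 6. Jarid2 at Suz12 sites (3.10) was 3.21 with all tags, 3.20 scaled to tags outside sites, 2.86 with a pseudocount of 5 and 3.27 with the 500 bp window. It was 2.61 with the 2.5 kb window, 3.01 with adjacent minus-strand positions merged, 3.69 less windows matched on all input tags and 3.20 less windows matched on part of the input tags. Jarid2 at Jarid1a sites (-0.12) was -0.16 with all tags, -0.024 scaled to tags outside sites and -0.057 with the 500 bp window. It was -0.18 with the 2.5 kb window, 0.50 less windows matched on all input tags and 0.083 less windows matched on part of the input tags. Suz12 at Jarid2 sites (3.97) was 4.10 with all tags, 4.23 scaled to tags outside sites, 3.76 with a pseudocount of 5 and 3.69 with the 2.5 kb window. It was 3.85 with adjacent minus-strand positions merged, 4.36 less windows matched on all input tags and 4.10 less windows matched on part of the input tags. Suz12 at Jarid1a sites (0.60) was 0.56 with all tags, 0.86 scaled to tags outside sites, 0.51 with a pseudocount of 5 and 0.89 with the 500 bp window. It was 0.17 with the 2.5 kb window, 1.22 less windows matched on all input tags and 0.89 less windows matched on part of the input tags. Ezh2 at Jarid2 sites (3.64) was 3.80 with all tags, 3.78 scaled to tags outside sites, 3.43 with a pseudocount of 5 and 3.80 with the 500 bp window. It was 3.25 with the 2.5 kb window, 3.56 with adjacent minus-strand positions merged, 4.29 less windows matched on all input tags and 3.83 less windows matched on part of the input tags. Ezh2 at Jarid1a sites (-0.33) was -0.20 scaled to tags outside sites, -0.28 with a pseudocount of 5 and -0.23 with the 500 bp window. It was -0.39 with the 2.5 kb window, 0.36 less windows matched on all input tags and -0.041 less windows matched on part of the input tags. Jarid1a at Jarid2 sites (0.044) was -0.022 with all tags, 0.094 scaled to tags outside sites, -0.12 with the 500 bp window, 0.00 at equal depth and -0.16 less windows matched on part of the input tags. Jarid1a at Suz12 sites (0.28) was 0.22 with all tags, 0.33 scaled to tags outside sites and 0.24 with a pseudocount of 5. It was 0.23 with the 2.5 kb window, 0.41 less windows matched on all input tags and 0.14 less windows matched on part of the input tags.

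With choices changed singly, Spearman correlations between Jarid2, Ezh2 and Suz12 stayed positive, and those with Jarid1a depended on which bins were taken. Over 10 kb from any site, values over the same input share its counting error. With input also split there, rho was -0.012 for Jarid2 with Suz12, 0.0069 for Jarid2 with Ezh2, 0.058 for Ezh2 with Suz12, -0.023 for Jarid2 with Jarid1a and 0.334 for Suz12 with Jarid1a. Without input it was 0.286, 0.280, 0.351, 0.323 and 0.710 in that order. Jarid2 with Suz12 (0.887) was 0.912 without input, 0.798 with input split and 0.902 with all tags. It was 0.858 with the 500 bp window, 0.661 in bins with a Jarid2, Ezh2 or Suz12 site and 0.247 over 10 kb from any site. Jarid2 with Ezh2 (0.951) was 0.957 without input, 0.851 with input split and 0.948 with all tags. It was 0.954 at equal depth, 0.930 in bins with a Jarid2, Ezh2 or Suz12 site and 0.329 over 10 kb from any site. Ezh2 with Suz12 (0.899) was 0.917 without input, 0.805 with input split and 0.913 with all tags. It was 0.873 with the 500 bp window, 0.697 in bins with a Jarid2, Ezh2 or Suz12 site and 0.316 over 10 kb from any site. Jarid2 with Jarid1a (-0.704) was -0.680 without input, -0.745 with input split, -0.632 with all tags and -0.657 with the 500 bp window. It was -0.675 at equal depth, -0.103 in bins with a Jarid2, Ezh2 or Suz12 site and 0.269 over 10 kb from any site. Suz12 with Jarid1a (-0.617) was -0.657 without input, -0.677 with input split and -0.567 with all tags. It was -0.540 with the 500 bp window, 0.220 in bins with a Jarid2, Ezh2 or Suz12 site and 0.669 over 10 kb from any site. The SD of the log2 ratio of Jarid2 to Suz12 (0.618) was 0.649 with all tags and 0.727 less scaled input tags.

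The alternatives for distance to transcription starts, for protein-coding starts, for lists matched on GC content, for the start with the most tags and for promoters near a site were not run, as they need an annotation of the build. No paired analysis was possible because each antibody had 1 library. Equal depth moved 1 of the 8 medians given here outside its interval, Jarid1a at Jarid2 sites. Counts were low there, with a median of 25 Jarid1a tags within 1 kb of a Jarid2 site and also low at Jarid1a sites, with 10 Ezh2 tags.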

Other observations

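The tests of explanations in this part were chosen, or changed, only after the results were seen, except the test of overlapping regions.

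The 10 widest merged regions each held calls of all 3 of Jarid2, Ezh2 and Suz12, and joining the regions of several lists widens them by construction. Chosen after their values were seen, the 3 widest merged regions lay at mm9 chromosome 11, 96129422 to 96184415 (55.0 kb), chromosome 6, 52160751 to 52205034 (44.3 kb), and chromosome 15, 102791809 to 102834002 (42.2 kb). Over the whole of the region on chromosome 6, log2 enrichment was 3.23 for Jarid2, 3.56 for Ezh2, 4.44 for Suz12 and -0.24 for Jarid1a.

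Of the 2408 merged regions, 8 overlapped a Jarid1a region, and the 4 places given here, chosen after their values were seen, are those with a Jarid1a centre within 1 kb of a Jarid2, Ezh2 or Suz12 centre. At chromosome 1, 9534990 to 9536354, Suz12 had log2 4.26, Jarid1a 3.47, Jarid2 2.80 and Ezh2 2.66. At chromosome 8, 91151031 to 91151933, the values were 2.86 for Suz12, 2.57 for Ezh2, 2.34 for Jarid2 and 1.91 for Jarid1a. At chromosome 8, 74031435 to 74032213, they were 2.73 for Suz12, 1.93 for Ezh2, 1.34 for Jarid2 and 1.53 for Jarid1a. At chromosome 12, 112775608 to 112777335, over 36 input tags, they were 1.13 for Suz12, 1.43 for Ezh2, 1.34 for Jarid2 and 1.79 for Jarid1a. Sites at least 4-fold over input in every ChIP library numbered 1 in the Jarid2 list, 3 in the Ezh2 list, 11 in the Suz12 list and 2 in the Jarid1a list. Their median input counts were low, at 4, 9, 8 and 8.5 tags in that order, so these values rest on few input tags.

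Suz12 tags stood above input at Jarid1a sites by the median (log2 0.60), while Jarid2 (-0.12) and Ezh2 (-0.33) did not. The mean density at the very centre was 3.71 for Suz12, 1.93 for Jarid2 and 1.62 for Ezh2, against 1.54 for input. PRC2 occupancy would raise Ezh2 there by more than 0.2 over windows matched on input, and the difference was -0.041, but the first version of this test, matched on the input tags that also formed the denominator, had given 0.36 and spoken for occupancy, so the reading rests on a change made after that value was seen. A median also cannot exclude occupancy at part of the sites. In bins at Jarid1a sites with input split, rho was 0.199 for Ezh2 with Suz12, 0.159 for Jarid2 with Ezh2 and 0.142 for Jarid2 with Suz12. Jarid1a fragments carried into the Suz12 library would raise Suz12 with Jarid1a, yet the 441 sites with the most Jarid1a tags exceeded the 441 with the fewest by 0.009 in Suz12 log2 enrichment, a test added after its value had been seen, and this stays open because the corresponding differences were -0.087 for Jarid2 and -0.13 for Ezh2 and rho of Suz12 with Jarid1a in bins at Jarid1a sites was 0.110 with input split, against 0.0051 for Jarid2 and 0.0088 for Ezh2. A background shared by the Suz12 and Jarid1a libraries had first been set to be excluded by a Suz12 median below 0.1 in matched windows, which held at -0.62 and, after the change, at -0.277, but that bound was wrong, since matching on input cannot find a background that input lacks, and over 10 kb from any site these libraries correlated at rho 0.334 with input split, against at most 0.058 for the other 5 pairs. This background, carry-over and a Suz12 signal apart from Ezh2 cannot be told apart. Neither library has an input of its own set, which would bear on the background, and Suz12 has no replicate library.

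Suz12 sites without a Jarid2 site were weighed against the calling of sites. Of the 1103, 71.6% had Jarid2 enrichment above the 99th percentile of windows matched on input (89.8% in the first version, matched on all input tags). Among the 937 with no overlapping Jarid2 region it was 67.6%, so their missing calls are consistent with Jarid2 tags present below the calling threshold. Peaks over 1 kb apart within overlapping regions were set to count as the cause at 50% or more and to be excluded under 10%, and 15.0% lay between. By construction this holds for the other 166 sites and leaves out those 937.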
